A study of Mus musculus with 4 samples.

How the data were processed

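BRG1/BRM ChIP-seq was available for primary mouse cortical neurons under basal conditions and after 1 h in 50 mM KCl, with 1 IP library and 1 input library per condition, 4 samples in all. Groups were taken from the sample titles and treatment labels. Island lists were analysed for the 2 IP samples, and separate files of the inputs were not used here.

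Reads were aligned with BWA, for which no version is given in the sources used here, to mouse build mm10 (GRCm38), and islands were called with SICER 1.0, per the submitters' processing notes. The names of the deposited lists carry a window of 200 bp, a gap of 600 bp and an FDR of 0.01, and an abbreviation that can stand for removal of duplicate reads, which was not settled. Each list was called on 1 IP library with a control, not on pooled samples. For every island the authors deposited the count of IP reads and the count of control reads, neither of them normalized. The p-value deposited by the authors sets the IP count against the control count scaled by library size. It was recomputed as a Poisson upper tail within 1 percent for 100.0% of the islands with control reads in either list, which shows that the control count enters as known without error. The FDR deposited beside it has the form of a Benjamini-Hochberg adjusted p-value over 1694 candidate islands in the basal list and 23178 in the KCl list, of which 42.0% and 90.5% passed. The fold deposited by the authors is the ratio of IP to control reads divided by a constant for each library, 0.880 for basal and 1.59 for KCl, which stands for the ratio of IP to control library size. For islands with 0 control reads the deposited fold assumes 0.25 reads. There were 1 such basal and 43 such KCl islands, and their folds are given against a floor of 3 control reads. This value takes the IP count as exact and is not a lower bound. The lower limit of the fold's interval, which lets both counts vary, is given beside it for the named islands and is smaller there. The labels do not say which input served as control for which list. At 8 islands with identical coordinates in both lists the control counts were equal in 0 cases, so the lists did not rest on the same control reads. Total depth could not be recovered from the lists, and the fewest IP reads in any island were 18 for basal and 20 for KCl. Folds depend on each library's own control and were used to describe and rank islands within a list.

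Island coordinates were converted to 1-based positions. Overlap of the lists required at least 1 bp and was computed with own code that gave the same islands as bedtools 2.31.1. Random expectation came from 100 placements of every island on its own chromosome with its width kept, between the lowest and highest position of any gene or island there. Genes were the 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, the same build. This table gives no strand and no transcripts, and no genome sequence was used here. The planned windows around transcription starts were therefore replaced by windows of 2 kb to either side of both gene ends, the nearest gene was the one with the nearest end within 50 kb, and random gene lists were matched on deciles of gene length for both regions. The planned motif counts were not run. Exons, introns and UTRs were not told apart for the same reason.

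The 12 gene lists were fixed before the data were examined, together with the tests, the alternatives other than those named as added, and the rule for named genes. All 263 entries were found by symbol or synonym, and 1 entry was a second name of a listed gene. For each list and library, the members with an island within 2 kb of a gene end, and with an island in the gene body or 10 kb around it, were counted and placed among 10000 random lists of the same size. Percentiles count ties by their midpoint and describe these libraries only. Named islands were the first 10 by fold among islands with at least 20 IP reads, leaving out the 1% with the highest control density, of the KCl islands without a basal overlap, the KCl islands with one, and the basal islands without a KCl overlap. Named members were up to 4 per list with the largest KCl fold at a gene end, or within 10 kb of the gene body where no member had one, and each member of the activity-regulated lists with a basal island. Names outside this rule are said in the text to be chosen after their values were seen. Where list members with basal islands were 5 or fewer, they were named for the same reason. Some genes that these rules select are not reported here.

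Shares have 95% exact (Clopper-Pearson) intervals. The interval of a fold comes from the exact binomial interval of the IP reads among the IP and control reads of the island, divided by the library constant, so that both counts vary. Without molecular identifiers, such intervals cover counting error only, and they do not allow for the choice of islands by their enrichment. With 1 library per condition no test between conditions was made. The procedures were tested on simulated data. A planted overlap of 300 of 711 islands was recovered as 300, a planted list of 30 genes lay at percentile 100, 2% of 400 unplanted lists lay above the 97.5th percentile, and 96.25% of 2000 simulated folds lay inside their 95% interval. Alternatives covered the FDR and fold thresholds, merging of islands, control density, the overlap required, the ranking and length of the KCl list, the windows around genes and the matching of random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.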

Results

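Genome-wide occupancy of the BAF (SWI/SNF) chromatin remodelling complex was mapped by ChIP-seq in wild-type mouse cortical neurons, cultured from E16.5 embryonic cortex and harvested after 6 days in vitro. The J1 antibody used for immunoprecipitation (IP) recognizes BRG1 and BRM, the alternative ATPase subunits of the complex, so the signal is that of both proteins. Neurons were either left at the basal KCl level or depolarized with 50 mM KCl for 1 h. For depolarization, cultures had received the sodium channel blocker tetrodotoxin (1 µM) and the NMDA receptor antagonist APV (100 µM) on day 5 to silence spontaneous activity, and the labels do not say whether basal cultures received them too. The design held 1 IP library and 1 input library per condition. No difference between basal and KCl therefore has a replicate check, and no p-value is given between conditions. The occupancy data were 2 lists of enriched regions, called islands, on mouse build mm10, with the IP reads, the control reads, and the fold enrichment over control computed by the authors for each island. Islands of the basal list held 142021 IP reads and 130865 control reads, and those of the KCl list held 1433200 IP reads and 400612 control reads. Total library depths are not given in the sources used here. Intervals in brackets are 95% exact (Clopper-Pearson) intervals that cover counting error only.

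The first comparison asked how much of the genome carried detectable BRG1/BRM in each state. After depolarization, BRG1/BRM islands were called at 20966 positions, including the delayed activity-regulated genes Bdnf and Scg2 and most of the fixed list of rapid activity-regulated genes, such as Fos and Npas4, whereas 711 islands were called in basal neurons. The KCl islands covered 41.4 Mb and the basal islands 2.21 Mb, so the KCl list was 29.5 times longer and its covered length 18.7 times larger. Basal islands had a median width of 2000 bp (interquartile range 1200 to 2800 bp), and KCl islands had a median width of 1600 bp (1000 to 2600 bp). Mean IP density was 64.2 reads per kb in basal islands and 34.6 reads per kb in KCl islands. The basal mean was set by very few regions, since the 3 largest basal islands held 45.1% of the basal IP reads, against 0.611% for the 3 largest KCl islands. The largest of these, on chromosome 9, held 43712 IP reads beside 44253 control reads. The median fold was 1.80 within the basal list (interquartile range 1.52 to 2.25) and 2.40 within the KCl list (1.84 to 3.39). Restricting both lists to islands of at least 2-fold left 259 basal and 13955 KCl islands, and an FDR of at most 1e-05 left 201 basal and 16125 KCl islands.

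The second comparison asked whether basal sites were a subset of those seen after depolarization. Of the basal islands, 449 of 711 (63.2% [59.5 to 66.7]) overlapped a KCl island, compared with a mean of 4.14% and a maximum of 6.33% over 100 random placements. In the other direction, 450 of 20966 KCl islands (2.15% [1.95 to 2.35]) overlapped a basal island, against a random mean of 0.138%. Shared islands with the largest KCl folds included one inside Atp6v0d1, which encodes a subunit of the vacuolar proton pump (chromosome 8, 105551001 to 105551400). It held 54 IP reads and 0 control reads in KCl, which is 11.3-fold against a floor of 3 control reads (lower interval limit 8.88). The basal island at this place held 19 IP reads and 0 control reads, 7.20-fold against that floor (lower interval limit 5.30). A shared island inside Lsamp, which encodes a limbic neuronal adhesion protein (chromosome 16, 42142801 to 42143200), had 0 control reads in KCl. It was 8.16-fold enriched against that floor (lower interval limit 6.33). Its basal counterpart held 18 IP reads and 1 control read (20.5-fold [3.23 to 852]). The KCl value rests on the floor and the basal value does not, so they are not like measures. Inside Morn5 (chromosome 2, 36059201 to 36059800), the shared island was 9.42-fold enriched in KCl [3.02 to 47.4] and 7.05-fold in basal neurons [2.72 to 23.2]. Of the other shared islands among the first 10, those nearest to L3mbtl4, Lratd1, Sis, Gm815, Prmt6, Frg1 and Slitrk1 lay farther than 50 kb from a gene end. Their KCl folds ran from 39.6 at L3mbtl4, where 63 IP reads stood against 1 control read [6.85 to 1587], down to 9.42 near Slitrk1 [3.49 to 35.7], and their basal folds from 9.85 near Lratd1 [3.02 to 50.8] down to 1.84 near Slitrk1 [1.18 to 2.91].

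A KCl island with a higher fold was more often one that overlapped a basal island, except at the top of the ranking. The share was 2.58% [1.94 to 3.35] in the highest decile by fold, 3.86% [3.08 to 4.78] in the second decile and 1.24% [0.812 to 1.81] in the lowest. Ranking by the authors' p-value instead gave 8.58% [7.42 to 9.87] in the highest decile, and ranking by IP reads per kb gave 4.67% [3.81 to 5.67]. When the KCl list was shortened to its first 711 islands, 14.6% of basal islands overlapped it under ranking by p and 2.25% under ranking by fold, so the overlap of 63.2% rests on the full length of the KCl list.

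KCl islands without a basal counterpart numbered 20516. By the deposited fold, which assumes 0.25 control reads where there were 0, the 10 largest were narrow, 400 to 800 bp, and each had 0 control reads. Their folds against a floor of 3 control reads do not place them above islands with control reads. The first lay 9.69 kb from Nanog, a pluripotency factor (chromosome 6, 122697401 to 122697800), with 54 IP reads. It was 11.3-fold enriched against that floor (lower interval limit 8.88). Others lay 45.2 kb from Dhrs7 (11.1-fold, lower limit 8.71) and 25.5 kb from Spin4 (9.63-fold, lower limit 7.52). Further ones lay within the collagen gene Col19a1 (8.16-fold, lower limit 6.33), within Shroom4 and 27.7 kb from Ids (both 7.12-fold, lower limit 5.48). The remaining 4, nearest to Pcdh9, Cdh18, Runx1t1 and Klf12, were farther than 50 kb from any gene end. Against the same floor they were 7.12-fold near Klf12 (lower limit 5.48) and 7.96-fold near the other genes (lower limit 6.16). Of the 262 basal islands without a KCl counterpart, the one with the largest fold lay 212 kb from Dthd1 (chromosome 5, 63100401 to 63101000), with 26 IP and 5 control reads (5.91-fold [2.23 to 19.7]). Islands of this kind also covered a gene end of Gm46866 inside Glis1, which encodes a zinc finger factor (2.73-fold [1.68 to 4.54]), of Zfp982 (2.68-fold [1.40 to 5.42]) and of Prtg, the gene of protogenin (2.45-fold [1.39 to 4.47]). Another among the first 10 lay 237 kb from the nearest gene end, that of Dpyd (3.31-fold [1.68 to 7.01]). The rest lay within 50 kb of an end of Gm10323 (2.90-fold [1.65 to 5.32]) and Atg7 (2.38-fold [1.11 to 5.40]), or inside Lingo2 (2.75-fold [1.68 to 4.62]), Fam178b (2.31-fold [1.5 to 3.61]) and Bank1 (2.21-fold [1.19 to 4.22]). Absence of a call in either list does not show absence of binding.

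The third comparison placed the islands relative to genes. After depolarization, BRG1/BRM islands gathered at the ends of protein-coding genes. In KCl, 4856 islands (23.2% [22.6 to 23.7]) lay within 2 kb of a gene end, compared with a mean of 8.06% and a maximum of 8.50% over random placements, and 5512 of 21887 protein-coding genes (25.2%) had such an island. In basal neurons 84 islands (11.8% [9.53 to 14.4]) did so, against a random mean of 8.70% and a maximum of 11.4%, and they lay at 90 genes. With an FDR of at most 1e-05 the basal share was 4.48%, so it depended on the threshold. Gene strand was not used here, so the start and the end of a gene count alike. KCl islands outside genes and farther than 50 kb from any protein-coding gene made up 28.2% [27.6 to 28.8] of the list, against 35.9% of random placements. Islands inside gene bodies away from the ends, at any distance from them, made up 35.6% [34.9 to 36.2], within the random range of 34.7% to 36.6%. KCl islands shared with basal neurons lay at gene ends in 9.56% [7.0 to 12.7] of cases (random mean 8.57%, range 5.56% to 12.9%) and those not shared in 23.5% [22.9 to 24] (random mean 8.04%, range 7.56% to 8.54%). Basal islands shared with KCl did so in 9.35% [6.82 to 12.4] (random range 4.90% to 11.1%). Those not shared did in 16.0% [11.8 to 21.0] (random range 5.73% to 13.4%).

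The median fold was lower at gene ends than elsewhere in both lists. In KCl, the median fold was 1.82 at gene ends and 2.67 away from them, and the median width was 2400 bp and 1400 bp. The share of islands at gene ends was 2.29% [1.69 to 3.02] in the highest decile by fold and 51.4% [49.3 to 53.6] in the lowest. The authors' test takes the control count as exactly known. When both counts were allowed to vary, the interval of the fold lay above 1 at 76.1% of KCl islands at gene ends and at 89.5% of those away from them. In basal neurons the median fold was 1.67 at gene ends and 1.84 away from them. The basal interval lay above 1 at 89.3% of islands at gene ends and at 85.0% of the others, the reverse of the order in KCl.

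**Figure D1:**
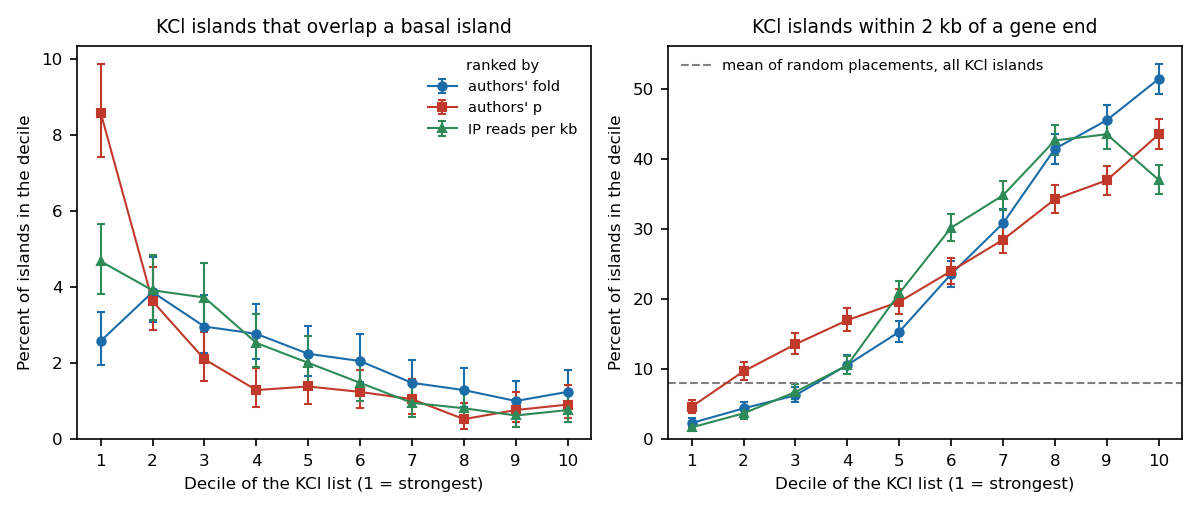
The left panel plots the percent of KCl islands that overlapped a basal island, and the right panel the percent that lay within 2 kb of a gene end, for each decile of the KCl list ranked by the authors' fold (circles), the authors' p-value (squares) or IP reads per kb (triangles), with 95% exact intervals for counting error. By fold, the share at gene ends rose from 2.29% in the strongest decile to 51.4% in the weakest, and the dashed line is the mean of random placements (8.06%).

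The fourth comparison asked which gene groups carried BRG1/BRM in each state, with 12 lists fixed before the data were examined. Genes induced within minutes to an hour of neuronal activity were covered after depolarization and mostly without a call in basal neurons. In KCl, 30 of 38 rapid activity-regulated genes had an island within 2 kb of a gene end, where random lists matched on gene length had a median of 8 (2.5th to 97.5th percentile 3 to 13), and 32 of 38 had one in the gene body or within 10 kb. Both counts lay at percentile 100 of 10000 random lists. In the list counts that follow, bodies include 10 kb around the gene unless the gene body alone or 50 kb is named. The largest folds at gene ends were those of Klf4, a zinc finger transcription factor (3.82-fold [2.06 to 7.73], chromosome 4, 55532001 to 55534000), Npas4, an activity-dependent transcription factor of neurons (3.38-fold [1.57 to 8.31], chromosome 19, 5001401 to 5002400), Ccn1, a matricellular protein (3.00-fold [1.79 to 5.30], chromosome 3, 145651201 to 145652600), and Srf, the serum response factor (2.30-fold [1.41 to 3.93], chromosome 17, 46554401 to 46556600). A broader island of 5000 bp covered one end of Fos (1.65-fold [1.22 to 2.27]). The members with no KCl island were Egr4, Arc, Maff, Amigo3, Sik1 and Csrnp1. Weak members were present as well, since the intervals of Ier2 (1.23-fold [0.920 to 1.66]), Ier5 (1.44-fold [0.907 to 2.33]), Atf3 (1.31-fold [0.907 to 1.93]) and Zfp36 (1.36-fold [0.932 to 2.02]) included 1. Fos, the 6 genes without an island and the 4 with weak islands lie outside the rule for named genes, and were chosen after their values were seen.

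In basal neurons, 3 of the 38 rapid genes had an island, all at gene ends, where random lists had a median of 0 and a 97.5th percentile of 1. None passed an FDR of at most 1e-05, which left 0 of 38. At Junb, a subunit of AP-1, the basal island was 1.72-fold enriched [1.16 to 2.56]. The KCl islands overlapping it were 1.79-fold [1.19 to 2.75] and 1.35-fold enriched [0.923 to 1.99]. At Ier5 the basal island was 1.70-fold enriched [1.03 to 2.86] and the KCl island overlapping it 1.44-fold [0.907 to 2.33]. At Egr3, a zinc finger factor, the basal island (1.55-fold [1.02 to 2.38], chromosome 14, 70081001 to 70084400) lay beside the KCl island (1.83-fold [1.29 to 2.63], 70074401 to 70080400) without overlapping it. When the KCl list was shortened to 711 islands, 0 of the rapid genes kept an island under ranking by fold or by p.

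**Figure D2:**
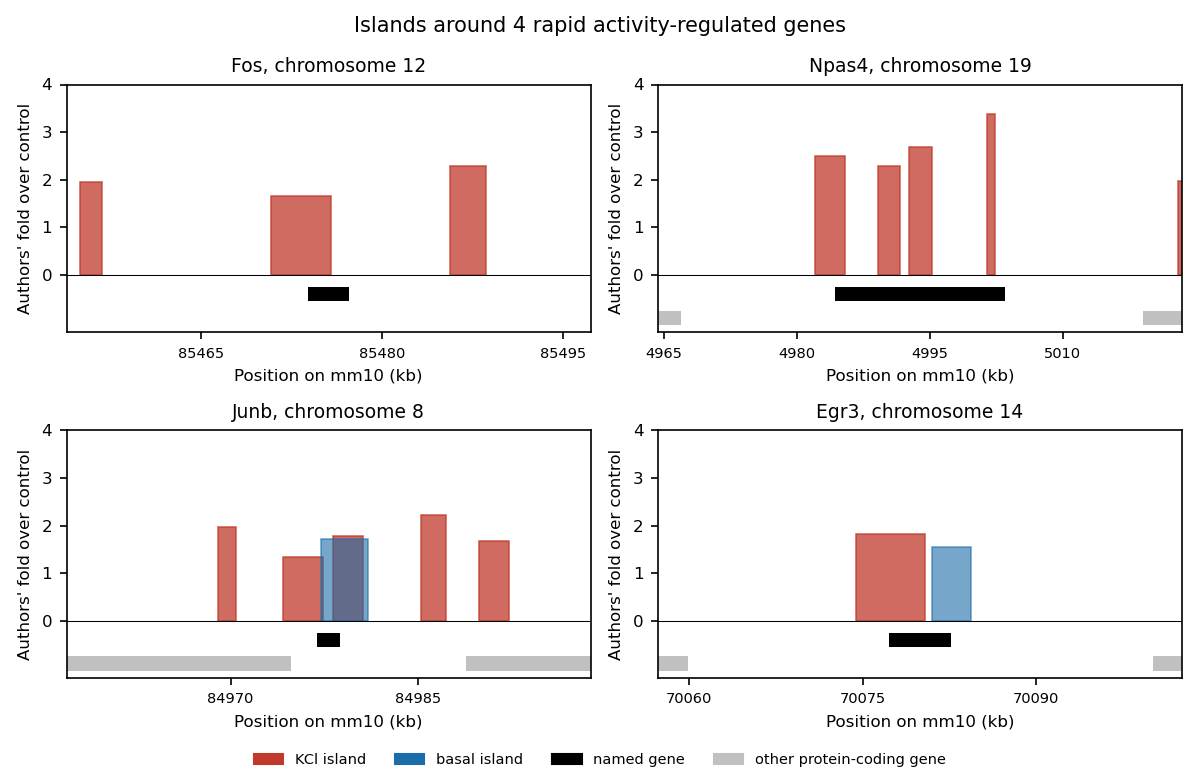
Islands are drawn to scale along mm10 (x axis, kb) around Fos, Npas4, Junb and Egr3, from 20 kb before to 20 kb after each gene, with the authors' fold over control as height, for KCl (red) and basal (blue) libraries, and gene extents below the zero line. Islands were called in KCl at each of the 4 genes, and in basal neurons at Junb (1.72-fold) and Egr3 (1.55-fold).

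Genes of the delayed activity response, which encode secreted and synaptic proteins among others, had an island at a gene end in 17 of 30 cases in KCl, where random lists had a median of 9 (4 to 14, percentile 99.95). Scg2, the secretogranin II gene (3.89-fold [2.72 to 5.74], chromosome 1, 79437201 to 79440600), and Cgref1 (3.89-fold [1.98 to 8.52]) were followed by Tiparp, which encodes an ADP-ribosyltransferase (3.14-fold [1.29 to 9.23]), and Nptx2, the neuronal pentraxin 2 gene (2.74-fold [1.40 to 5.85]). An island of 8200 bp covered an end of Bdnf, the neurotrophin gene (1.91-fold [1.47 to 2.49]), which was named after its value was seen. In the gene body or within 10 kb, 19 of 30 had an island (percentile 98), and 22 of 30 did within 50 kb (percentile 81.8). The only member with a basal island was Dclk1, which had 2 in the body or within 10 kb. The 1 at a gene end (1.88-fold [1.22 to 2.95], chromosome 3, 55539801 to 55542600) overlapped no KCl island. Dclk1 also had 12 KCl islands in the body or within 10 kb. Of these, the 1 at a gene end lay at the opposite end (55241401 to 55244800) and was 1.88-fold enriched [1.27 to 2.87].

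Cortical neuron genes were widely covered after depolarization. Of these, 25 of 30 had a KCl island at a gene end (random median 10, 6 to 16) and 27 of 30 in the body or within 10 kb (random median 17, 13 to 22), both at percentile 100. The neurofilament gene Nefl (3.25-fold [1.94 to 5.71]) and the cortical transcription factor genes Tbr1 (3.21-fold [1.55 to 7.46]), Cux1 (3.19-fold [2.08 to 5.06]) and Fezf2 (3.03-fold [2.02 to 4.69]) led the list. Basal islands were called in the bodies of 3 of 30 members against a random median of 1, among them Map2 (1.75-fold [1.13 to 2.76]) and Bcl11b (2.03-fold [1.19 to 3.54]), and in 0 of 30 at an FDR of at most 1e-05.

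Markers of interneurons and glia, which such cultures could also hold, had counts within the central range of random lists in KCl, except for microglia genes at gene ends. Interneuron genes had KCl islands at the ends of 4 of 20 members (percentile 28.1), namely Maf (2.56-fold [1.41 to 4.97]), Erbb4 (2.15-fold [1.43 to 3.32]), Reln (1.83-fold [1.12 to 3.08]) and Dlx1 (1.55-fold [1.03 to 2.38]). In the body or within 10 kb, 7 of 20 interneuron genes had an island (percentile 31.2). Astrocyte genes had them at 5 of 15 ends (percentile 73.3), led by the glutamate transporter gene Slc1a3 (3.56-fold [1.74 to 8.22]), with the water channel gene Aqp4 (2.37-fold [1.39 to 4.24]), Slc1a2 (2.07-fold [1.24 to 3.61]) and Sox9 (1.67-fold [1.30 to 2.17]), and in 6 of 15 bodies (percentile 48.4). Of the oligodendrocyte lineage genes, 2 of 15 had an island at an end (percentile 14.6), Pdgfra (2.28-fold [1.44 to 3.74]) and Olig1 (1.72-fold [1.09 to 2.78]). In the body or within 10 kb, 5 of 15 had an island (percentile 34.6). Microglia genes had 0 of 15 at gene ends (percentile 0.855) and 3 of 15 in the body or within 10 kb (percentile 9.59), near Ptprc (4.55-fold [2.48 to 9.15]), Tyrobp (2.72-fold [1.54 to 5.14]) and Aif1 (1.52-fold [0.970 to 2.42]). Liver and muscle genes had 1 of 20 in either region, the skeletal actin gene Acta1 (2.36-fold [1.23 to 4.89]), fewer than most random lists (percentile 3.04 at ends and 0.22 in bodies). The sole basal island among these lists lay in the body of Slc4a4 (1.67-fold [1.08 to 2.63]), an astrocyte list member, and it was not called at an FDR of at most 1e-05.

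Neural progenitor genes had KCl islands at the ends of 10 of 18 members (percentile 99.7), with Hes1 (2.20-fold [1.29 to 3.94]), Ccnd1 (2.11-fold [1.14 to 4.15]), Sox2 (2.01-fold [1.32 to 3.14]) and Notch1 (1.87-fold [1.31 to 2.71]) at the head. In the body or within 10 kb, 11 of 18 had an island (percentile 98.7, and 96.6 against random lists not matched on length). Genes of the BAF complex itself had islands at 13 of 26 ends (percentile 97.9). In the body or within 10 kb, 17 of 26 had an island (percentile 96.8), and 13 of 26 did in the gene body alone (percentile 83.4). With a window of 1 kb the count at ends was 11 of 26 (percentile 93.0), so the standing of this list depended on the window. Its members with the largest folds were Arid1a (5.38-fold [2.46 to 14.0]), Smarcc2 (3.70-fold [1.81 to 8.53]), Arid1b (3.33-fold [2.45 to 4.6]) and Ss18 (2.87-fold [1.65 to 5.28]), which encode subunits other than the ATPases. Voltage-gated calcium channel genes lay within the range of length-matched random lists in KCl. They had islands at 7 of 15 ends (percentile 64.4), and 4 of 15 at an FDR of at most 1e-05. In the body or within 10 kb, 13 of 15 had an island (percentile 89.6). Against random lists not matched on length the percentiles were 96.7 at ends and 99.995 in bodies, so the standing in bodies depended on the matching. This list was led at gene ends by Cacnb4 (2.51-fold [1.58 to 4.16]), Cacna1h (2.26-fold [1.26 to 4.31]), Cacna1g (1.93-fold [1.04 to 3.82]) and Cacna2d1 (1.79-fold [1.43 to 2.25]). Of the channel genes, 3 of 15 also had a basal island (random median 1, 0 to 3), at Cacna1a (2.09-fold [1.17 to 3.87]), Cacnb2 (3.51-fold [1.74 to 7.69]) and Cacna2d3 (2.21-fold [1.22 to 4.14]), of which 1 was left at an FDR of at most 1e-05. The progenitor and BAF complex lists had 0 members with a basal island.

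Housekeeping genes had KCl islands at 10 of 20 ends (random median 4, 1 to 8, percentile 99.8) and in 11 of 20 bodies (percentile 98.9, but 91.5 with 50 kb around the body and 92.6 against lists not matched on length). Members with large folds included Eef1a1 (1.88-fold [1.43 to 2.48]), Tuba1b (1.59-fold [1.06 to 2.44]) and Tfrc (1.57-fold [0.942 to 2.70]), and 0 members had a basal island. At an FDR of at most 1e-05 the count at gene ends fell from 10 to 2 (percentile 43.5), whereas it was 25 of 38 for rapid genes and 22 of 30 for cortical neuron genes (percentile 100 for both). Among islands whose interval lay above 1 with both counts varying, a setting added after seeing the data, the housekeeping count at gene ends was 5 (percentile 87.0). Random lists were matched on gene length and not on expression or base composition, so a high percentile in KCl does not set a list apart from other genes that are active in neurons. No test compared the lists with one another or between conditions.

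**Figure D3:**
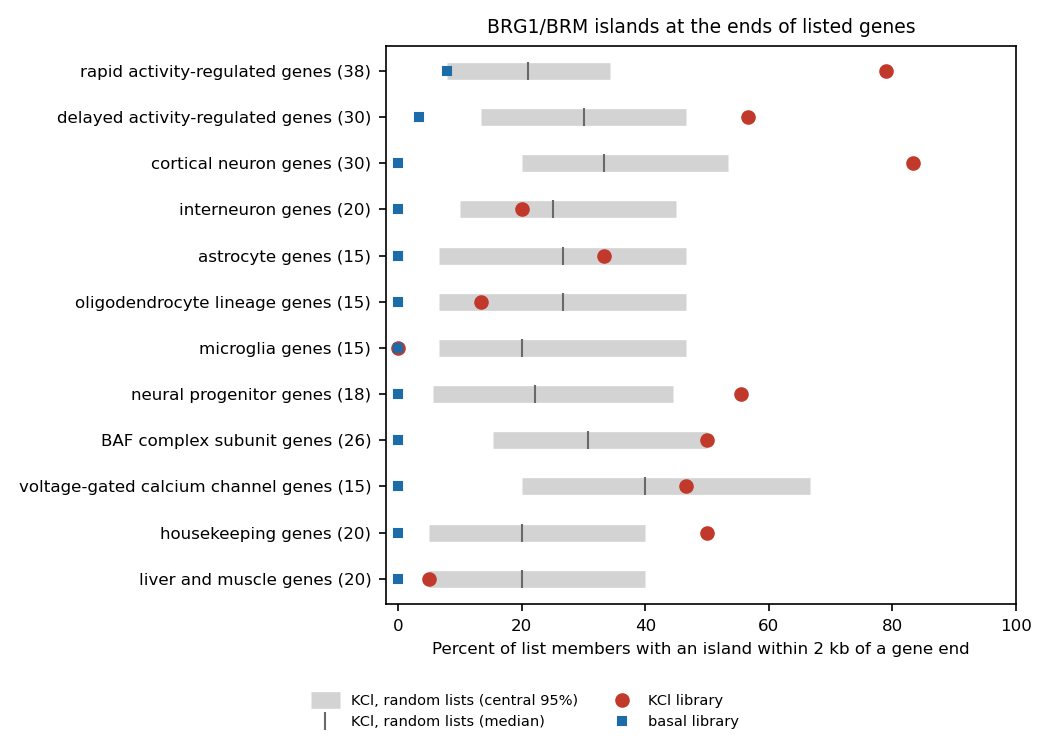
For each of the 12 gene lists (number of members in brackets), the x axis gives the percent of members with an island within 2 kb of a gene end in the KCl library (red circles) and in the basal library (blue squares), with the 2.5th to 97.5th percentile (grey bars) and the median (ticks) of random lists matched on gene length in the KCl library. In KCl, 30 of 38 rapid activity-regulated genes and 25 of 30 cortical neuron genes lie right of the grey bars, and the basal counts are 3 of 38 and 0 of 30.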

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

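The alternatives that required a 95% interval above 1 with both counts varying, and the shortening of the KCl list by p for the gene lists, were chosen after seeing the data. Over 34 results and 195 alternative values, 110 stayed within 1.5 times a count or within the 95% interval of a share, 85 moved and 0 changed direction, since a count or share has none to change. The cause of each move was not tested unless the alternative removes islands or widens a window by construction. No paired analysis was possible because each condition had 1 library and the labels give no shared replicate numbers. For the same reason no library could be left out. The alternatives that needed strand, transcripts or sequence (the most 5' start of each gene, and the alternatives for motifs) were not run. Basal islands had a median of 51 IP and 31 control reads and KCl islands 59 IP and 16 control reads, and with total depth unknown a site without a call is not shown to be unbound.

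At an FDR of at most 1e-05 the basal list held 201 islands, 82.6% of them overlapped a KCl island and 1.04% of KCl islands overlapped a basal one. The share at gene ends was then 4.48% in basal and 18.3% in KCl, 4 calcium channel genes had an island at an end, and housekeeping genes had 2 at ends and 3 in bodies. A fold of at least 2 left 259 basal and 13955 KCl islands, with overlaps of 82.2% and 1.53%. With as many KCl islands as basal ones, ranked by p, 14.6% of basal and 14.3% of KCl islands overlapped, and ranked by fold 2.25% of basal islands did and 2.11% of KCl islands lay at gene ends. Ranked by p, the highest decile of the KCl list overlapped basal islands in 8.58% of cases, and ranked by IP reads per kb the highest decile did in 4.67% and the lowest in 0.763%. The share of islands at gene ends was 21.7% in KCl with a window of 1 kb, and 16.6% in basal and 26.7% in KCl with 5 kb. It was 20.4% in KCl among islands whose interval with both counts varying lay above 1.

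With the KCl list shortened to the first 711 by fold, the count at gene ends was 0 for each of the 12 lists. In bodies it was 1 for cortical neuron genes, 3 for calcium channel genes and 0 for the other lists, and 0 lists lay above the 97.5th percentile in either region, where the full list had 6 at ends and 5 in bodies. Shortened by p, the counts at ends were 2 for delayed activity-regulated genes, 1 for BAF complex genes and 0 for the others, and in bodies 3 for delayed activity-regulated genes, 3 for calcium channel genes, 1 each for cortical neuron, interneuron and BAF complex genes, and 0 for the others. Then 2 lists at ends and 1 in bodies lay above the 97.5th percentile. With 50 kb around the gene body, counts were 14 for interneuron, 11 for astrocyte, 10 for oligodendrocyte lineage, 9 for microglia and 5 for liver and muscle genes, and 3 lists lay above the 97.5th percentile. With the gene body alone they were 3 for oligodendrocyte lineage and 1 for microglia genes. With a window of 5 kb, 3 microglia genes had an island at an end. With islands whose interval with both counts varying lay above 1, housekeeping genes had 5 at ends and 6 in bodies, and 3 lists lay above the 97.5th percentile in bodies.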

Other observations

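The tests of false calls among basal islands, of basal calls with both counts varying, of fold at basal islands with dense control reads, of island pairs with nearly the same extent, of gene ends in the ranking by IP density, and of base composition were chosen after the result was seen, as were the gene regions described next. After depolarization, the broadest BRG1/BRM island of at least 2-fold spanned 38600 bp on chromosome 13 (83712801 to 83751400), 45.7 kb from an end of Mef2c, the gene of a neuronal MADS-box factor. It held 1504 IP and 431 control reads (2.19-fold [1.97 to 2.45]), had the lowest p-value of the KCl list, and overlapped a basal island. Other broad islands covered an end of Nr2f1, a nuclear receptor gene (15400 bp, 2.05-fold [1.67 to 2.52]), and the bodies of Celf2 (12400 bp, 2.03-fold [1.66 to 2.49]) and Tcf4 (9600 bp, 2.08-fold [1.67 to 2.60]). Ends of Myt1l, a neuronal zinc finger factor gene (9000 bp, 2.19-fold [1.77 to 2.74]), and Tiparp (8600 bp, 2.04-fold [1.57 to 2.66]) were covered as well. These 5 islands overlapped no basal island. A broad island of 15200 bp that lay 217 kb from the nearest gene, Prkd1, did overlap a basal island (2.19-fold [1.82 to 2.64]).

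The protein-coding genes with the most KCl islands were Dlg2, a postsynaptic scaffold gene, with 42, Ptprd with 37, Lsamp with 32 and Cadm2 with 30. These genes are long, and their density was 1.46 to 3.11 islands per 100 kb, against a median of 0.932 over 2429 protein-coding genes of at least 100 kb. Others with many islands lay near that median, such as Cntnap2 (23 islands, 1.03 per 100 kb) and Lrp1b (23 islands, 1.12 per 100 kb). Among protein-coding genes of at least 100 kb, density was highest in Dok5 (8.11 per 100 kb, 12 islands), Sybu (7.74, 9 islands), the zinc finger gene Zeb2 (7.47, 10 islands) and the neuronal membrane glycoprotein gene Gpm6a (7.46, 21 islands). Mef2c itself had 6.13 per 100 kb with 10 islands. The X chromosome held 227 KCl islands (1.08% [0.947 to 1.23]) and 17 basal islands (2.39% [1.40 to 3.80]) while it made up 6.32% of the span searched. Median control density at KCl islands was 7.11 reads per kb on the X and 9.38 on autosomes, a ratio of 0.758. At basal islands it was 18.8 on the X and 16.25 on autosomes, a ratio of 1.16. Whether coverage of the X contributes to the low shares was not tested, so they do not show less BRG1/BRM there.

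The KCl list held 29.5 times as many islands as the basal list. If fewer basal IP reads were the only difference, islands called in both lists would be equally enriched over control, yet at 442 groups of shared islands the pooled enrichment was 1.80 in basal and 2.61 in KCl, a ratio of 1.45 (95% interval over resampled islands 1.33 to 1.60). Island limits differ between the lists, and the ratio was 1.34 (1.22 to 1.5) at 59 pairs with a reciprocal overlap of at least 80%, while at the 8 islands with identical coordinates it was 1.25 with a counting interval that included 1 (0.956 to 1.65). The values at 442 groups and 59 pairs argue against depth as the whole cause, and do not measure a change in occupancy. Control reads at the 442 groups, scaled by the library constants, gave an expected background of 15.2 IP reads per kb in basal and 16.7 in KCl, a ratio of 1.10. At the 8 identical islands the implied ratio of KCl to basal IP depth was 1.37. Both ratios take control density at shared islands to stand for library size, and total depths remain unknown. A weaker immunoprecipitation in the basal library for technical reasons cannot be told apart from more BRG1/BRM on chromatin after KCl, because there was 1 IP library per condition.

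Of the basal islands, 262 had no KCl counterpart although the KCl list was far longer, and their median fold was 1.52 against 2.03 at shared basal islands. The authors' FDR allows 7.11 false calls in the basal list but takes the control count as known, and with both counts varying 36 of the 262 (13.7%) and 172 of the 449 shared islands (38.3%) passed the same threshold, which then allows 2.08 false calls. False calls from counting error are thus too few to account for those 36. The test does not cover regions of very high coverage, and how many of the 36 are among the 19 densely covered islands described next was not counted. For the other 226, false calls cannot be told apart from true sites, because failing this test does not show an island to be false. Control density was 1.21 times (1.16 to 1.32) that of the shared basal islands, below the 1.5 times that regions of very high coverage would need for the whole set, but 19 islands had over 100 control reads per kb, against 0 of the 449 shared ones, with a median fold of 1.15 (interquartile range 1.13 to 1.20) and 66.1% of the set's IP reads, which is consistent with very high coverage as the source of these 19. Loss of BRG1/BRM after KCl and a difference between single libraries stay open and untested.

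The highest folds of the KCl list lay at narrow islands away from gene ends. Chance low control counts may account for the islands with 0 control reads, since 43 were observed and 35.8 expected from Poisson counts at the median control density, a ratio of 1.20. Ranking by IP reads per kb, whose order uses no control reads, put 1.67% [1.17 to 2.31] of the top decile at gene ends, below 6.40% (4.77% to 7.77%) of its random placements. That ranking also followed width, with a median of 600 bp in the highest decile and 3000 bp in the lowest, and every island had passed a test against control. It cannot decide whether low control coverage raised the highest folds. By fold, the highest decile had a median of 4 control reads at a median width of 800 bp, and the lowest 31 at 2800 bp. Whether base composition of the IP library has a part cannot be told with 0 genome sequences at hand. Binding of the complex at distal regulatory elements was not tested, as no map of such elements was used here.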
